A study of Danio rerio with 12 samples.

How the data were processed

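The series holds 12 RNA-seq libraries of zebrafish (Danio rerio), each made from a pool of 25 whole larvae at 3 days post fertilization (dpf). Per the labels, total RNA was extracted with TRIzol and a column kit. There were 4 groups of 3 libraries: control larvae, larvae carrying a transgene labelled Tg(ifih1_mut) (here ifih1mut), and the same 2 kinds of larvae stimulated with poly I:C, a synthetic double-stranded RNA. The labels do not say whether the pools of a group came from separate clutches, so p-values measure only the spread between these pools. Dose, route and duration of poly I:C are not given in the sources used here.

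The deposited data were 3 comparison tables of 6 libraries each. Per the file headers, the authors gave for each gene a raw read count per library, a log2 fold change, and a p-value with its adjusted p-value. The aligner, the counting program, the genome build, the strand setting and the authors' test are not given in the sources used here. The counts were whole numbers with library totals between 31876869 and 100839015. The 36 columns of normalized values that the authors deposited for the same libraries were not used. The log2 fold changes and p-values deposited by the authors served only for a side-by-side count of calls.

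The tables were joined by gene identifier into 32349 genes. Of 187002 counts listed in more than 1 table, 0 differed. A gene was listed in a table only when its 6 libraries held at least 2 counts together, so a gene listed elsewhere has at most 1 count where it is missing. The 6372 missing values, in 1484 genes, were set to 0. Of the 32349 genes, 5306 had identifiers of assembled genes without a name and 3569 lay on alternate contigs, where reads can be shared with the matching part of a chromosome. Gene names and coordinates came from the deposited tables. The reference names covered 25043 identifiers.

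Groups were assigned from the titles. The table columns name the group and a library number (A72 to A83) but not the replicate number of the titles, so libraries are named by group and library number. Genes were filtered with filterByExpr at its defaults (minimum count 10, minimum total 15), which left 26508. Counts were normalised by TMM and tested with the quasi-likelihood F-test of edgeR 4.0.16 in R 4.3.3, with 1 coefficient per group, all 12 libraries in the fit, 8 residual degrees of freedom and a Benjamini-Hochberg adjusted p under 0.05. There were 5 contrasts: ifih1mut against control, poly I:C in control larvae, ifih1mut against control with poly I:C, poly I:C in ifih1mut larvae, and the difference between the poly I:C effects of the genotypes. Expression levels are CPM (the count of a gene scaled to its library's TMM-adjusted total).

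Before the data were examined, 24 gene lists were fixed. They cover interferon-stimulated genes, interferons with their receptors and JAK-STAT, RNA sensing, MHC class I, inflammatory cytokines and NF-kB, inflammasome, complement and acute phase, stress and clock programmes, and marker genes of the tissues of a whole larva. Of 799 list symbols, 719 matched a gene. Lists were tested with camera (limma 3.58.1) at a preset correlation of 0.01, adjusted over the 24 lists of a contrast, and again with the correlation estimated from the data. The rotation test fry, also from limma, was a further alternative. List calls below are given with the estimated correlation unless the preset is named. Camera compares a list with other genes, while fry asks whether its members move, on balance, one way.

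Named genes followed a rule fixed at the same time: ifih1, the 12 higher and 8 lower genes with the largest change among called genes at an average log2 CPM of at least 0 with no overlap between the groups and a gene symbol that is no clone name, up to 4 called members of each list by adjusted p, and 8 fixed genes (isg15, rsad2, mxa, stat1b, irf7, il1b, tnfa and cxcl8a). For the difference of effects the rule took 5 in each direction, without the condition on overlap. Genes named outside the rule are marked as chosen after their values were seen.

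Alternatives fixed before the data were examined were RLE size factors, the Wald test of DESeq2 1.42.0, no filter, a minimum CPM of 1 in 3 libraries, only the groups compared, an added log2 fold change of 1, and leaving out each library. Alternatives chosen after seeing the data were a block for library sets (the position of a library's number in its group, described with the results), DESeq2 with that block, leaving out each set, and thinning every library to 31876869 counts. The fits were tested on simulated counts with 100 genes changed 2-fold and 100 changed 4-fold. The changed genes were drawn from those with an average log2 CPM above 0 in the real libraries. For ifih1mut against control, where 26160 simulated genes passed the filter, edgeR recovered 46% of the 2-fold and 83% of the 4-fold genes with 1 false call. For poly I:C in control larvae, with 26169 genes, the shares were 50% and 92%, again with 1. For ifih1mut against control with poly I:C, with 26149 genes, they were 44% and 84%, with 0 false calls. Under the set block, the shares in these 3 comparisons were 76% and 97% with 13 false calls, 80% and 98% with 19, and 75% and 95% with 5. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

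The mitochondrial share of counts was 3.8% to 5.1% and the 10 most abundant genes of a library took 7.7% to 9.1%. Because genes of the mx, ifit and hbbe families have near-identical copies and the handling of shared reads is not given in the sources used here, values of single members are uncertain.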

Results

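Whole zebrafish larvae at 3 dpf were profiled by RNA-seq in a design of 2 genotypes with and without poly I:C, in 12 pools of 25 larvae, 3 per group. The series sets out to model Aicardi-Goutières syndrome, an inherited disease with raised interferon signalling, through ifih1. This gene encodes MDA5, a cytoplasmic sensor of long double-stranded RNA. Library totals were 100839015, 53403950 and 31876869 counts in the control group (A81, A82, A83) and 34497993, 75753738 and 65922758 in ifih1mut (A75, A76, A77). With poly I:C they were 32253177, 33057156 and 33192488 counts in control (A78, A79, A80) and 36743869, 33401891 and 37361779 in ifih1mut (A72, A73, A74).

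The ifih1 gene (ENSDARG00000018553, chromosome 9, 51147380 to 51217396 in the deposited coordinates) was higher in every pool labelled ifih1mut than in every control pool. Its level was 2.34 ± 0.376 CPM in control and 14 ± 2.99 CPM in ifih1mut pools (SD, n = 3). With poly I:C it was 2.06 ± 0.173 CPM in control and 25.4 ± 7.9 CPM in ifih1mut pools (SD, n = 3). The fold was 5.99 without poly I:C (log2 2.58, SE 0.24, edgeR adjusted p = 0.0097) and 12.3 with it (log2 3.62, SE 0.26, edgeR adjusted p = 0.00051). Reads of the transgene and of the native gene are not separated in these counts.

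Expression also varied along a line that the groups do not define. After the group means were removed, libraries at the same position of their group's numbering correlated with each other over 17126 genes (r from 0.282 to 0.832 in 18 pairs), and libraries at different positions did not exceed 0.128. These are correlations across genes, which are not independent replicates. Each set holds 1 library of every group: A81, A75, A78 and A72 form set 1, A82, A76, A79 and A73 form set 2, and A83, A77, A80 and A74 form set 3. The first principal component (35.9% of variance) parted set 1 from the others and the second (20.2%) parted the ifih1mut pools with poly I:C from the other 9 libraries. The biological coefficient of variation was 0.2625 without and 0.1514 with a block for the sets. The xenobiotic-response gene cyp1a is an example chosen after its values were seen, at 1010 to 1250 CPM in the 4 libraries of set 3 and 17.1 to 84.4 CPM in the other 8.

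**Figure D1:**
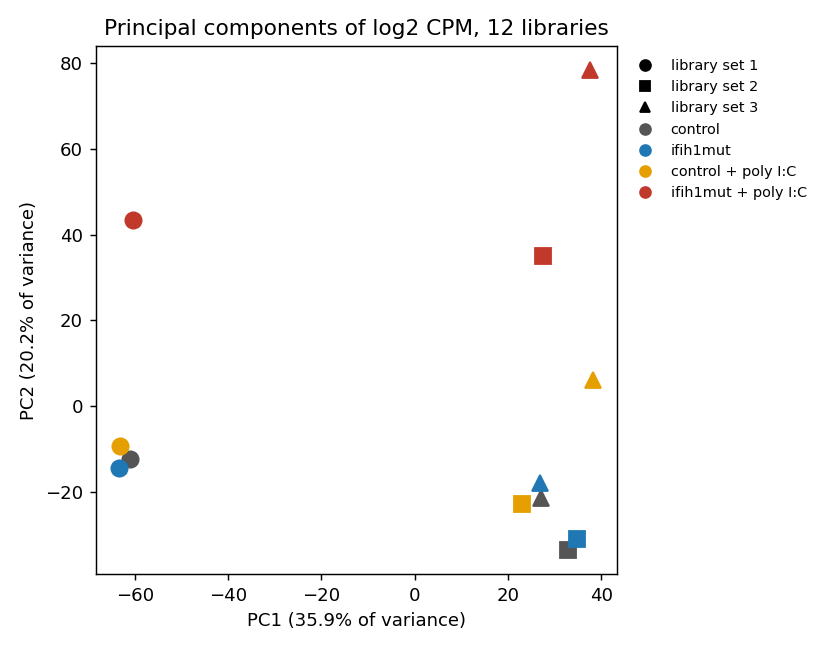
Scores of the 12 libraries on the first and second principal component of log2 CPM, with colour for the group and marker for the library set. Set 1 lies between -63.29 and -60.45 on the first component, and the 3 ifih1mut pools with poly I:C lie at 35 or above on the second.

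The first question was whether ifih1mut larvae differ from control larvae without stimulation. Interferon-stimulated genes did not differ detectably between the unstimulated pools of the genotypes. The ubiquitin-like modifier isg15 was at 1.24 ± 1 CPM in control and 1.08 ± 0.567 CPM in ifih1mut (SD, n = 3), and the transcription factor stat1b at 0.574 ± 0.182 and 0.539 ± 0.142 CPM. The antiviral GTPase mxa was at 0.5 ± 0.187 and 0.489 ± 0.224 CPM, and irf7, a transcription factor of interferon genes, at 5.16 ± 0.246 and 4.35 ± 0.285 CPM. Of 49 interferon-stimulated genes tested, 0 passed over all genes and 0 adjusted over the list alone, with a median log2 fold change of -0.06 (camera adjusted p = 0.988 with an estimated correlation). Within the sets the list's medians were -0.08, -0.01 and -0.04. Medians within sets are, here and below, on the log2(CPM + 0.5) scale, which shrinks the changes of low genes. They are therefore not the same measure as the medians of edgeR fold changes.

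In this comparison ifih1 itself was the 1 gene past the threshold in edgeR, of 26508, and 135 genes had an unadjusted p under 0.05, where chance alone gives 1325. In each of the 5 contrasts this fit gave fewer than 1325 such genes (135 to 992). It leaves the variation between library sets in its residual, which can raise its p-values because the sets are balanced over the groups. The low counts therefore do not show that few genes differ. With the set block the call stayed at ifih1 alone and 350 genes had an unadjusted p under 0.05, still below 1325. In this comparison the variation between library sets therefore does not account for the whole shortfall, and the cause of the rest was not tested. DESeq2 called 2 genes. The pro-inflammatory genes il1b (log2 -0.80, SE 1.2) and cxcl8a (log2 -0.32, SE 0.45) did not pass (edgeR adjusted p = 1 for each), and il1b ranged from 0.4205 to 10.07 CPM among the control pools. Both directions turned without A81 (log2 0.44 for il1b and 0.34 for cxcl8a), and il1b was at -1.85 without A75. The preset correlation called 3 lists: lens crystallins at a median log2 fold change of -0.08 (camera adjusted p = 0.0046), liver genes at 0.11 (0.0202) and epidermis and ionocyte genes at 0.06 (0.0422). With an estimated correlation each had an adjusted p of 0.988. The authors' deposited table listed 5 genes at an adjusted p under 0.05, with ifih1 higher and rab34a, nbr1a, BX537263.3 and BX537263.4 lower, the last 4 named after their values were seen. Without A81, A82, A83 or A76, edgeR called 0 genes. Over all fits with 1 library left out, the log2 fold change of ifih1 stayed between 2.41 and 2.72.

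The second question was what poly I:C does in control larvae. The interferon-stimulated genes stat1b and rsad2, an antiviral enzyme, were higher in 1 of the 3 stimulated control pools, A80. There, stat1b reached 5.994 CPM against 0.7109 in A78 and 0.6 in A79, and rsad2 reached 1.807 CPM against 0.2473 and 0.06. The level of isg15 was 1.113 CPM in A78, 3.3 in A79 and 3.283 in A80, and that of irf7 was 4.142, 5.82 and 5.18 CPM. The group means were 2.57 ± 1.26 CPM for isg15 and 2.43 ± 3.08 CPM for stat1b (SD, n = 3), and neither was called against control in edgeR (log2 1.21, SE 0.61 for isg15 and log2 2.19, SE 0.88 for stat1b, adjusted p = 1 for each). With the set block the log2 fold changes were 1.25 (SE 0.36) and 1.76 (SE 0.49), also not called. Without A83 that of isg15 was 1.98, and without A80 that of stat1b was 0.29. The irf7 level was 5.05 ± 0.847 CPM against 5.16 ± 0.246 CPM in control (SD, n = 3), and mxa was at 0.797 ± 0.54 CPM.

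No gene passed in edgeR in this comparison (0 of 26508, with 367 at an unadjusted p under 0.05), nor with the set block (0, with 1054), and DESeq2 called 0, or 24 with the set block. The authors' deposited table listed 7 genes at an adjusted p under 0.05, 6 of them higher. Of the 49 interferon-stimulated genes, 0 passed over all genes or adjusted over the list alone. Their median log2 fold change was 0.17, called with the preset correlation (camera adjusted p = 0.000684) but not with an estimated one (adjusted p = 0.751). The call at the preset correlation was lost without A80 (adjusted p = 0.60), and the medians within the sets were 0, -0.01 and 0.3. This call was not particular to the list: the preset called 9 of 24 lists and the estimated correlation 0. Complement and acute phase had the same median (camera adjusted p = 0.000359 at the preset). Photoreceptor genes had a negative log2 fold change in 32 of 32 members, with a median of -0.36 (camera adjusted p = 1.12e-20 at the preset, adjusted p = 0.74 with an estimated correlation) and set medians of -0.31, -0.09 and -0.84. Adjusted over the list alone, 0 of the 32 were lower in edgeR and 22 with the set block, where the adjusted p with an estimated correlation was 0.29 in camera. On simulated counts, edgeR recovered 92% of genes changed 4-fold and 50% of those changed 2-fold in this comparison. The changed genes were drawn from those with an average log2 CPM above 0. These shares need not hold for genes as low as stat1b and rsad2 in unstimulated control pools (0.574 and 0.222 CPM). Their 4.55-fold and 3.01-fold estimates were not called.

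The third question was how the genotypes compare under poly I:C. Stimulated ifih1mut pools carried a broad set of interferon-stimulated transcripts at levels far above stimulated control pools. The transcript of isg15 was at 185 ± 82 CPM against 2.57 ± 1.26 CPM (SD, n = 3), 71.7-fold higher, and stat1b at 217 ± 153 CPM against 2.43 ± 3.08 CPM, 89.1-fold higher. The RNA sensor dhx58, also known as LGP2, was 80.2-fold higher (134 ± 65.6 against 1.66 ± 1.59 CPM) and rsad2, which encodes viperin, 101-fold (71.9 ± 41.2 against 0.705 ± 0.959 CPM). Of the Mx GTPases, mxa rose 86.4-fold, mxb 110-fold and mxe 80.4-fold, while mxc (log2 1.46, SE 0.48, edgeR adjusted p = 0.72) and mxg (log2 0.72, SE 0.55, 1), chosen after their values were seen, did not pass. The log2 fold changes were 6.16 (SE 0.62, edgeR adjusted p = 0.0012) for isg15, 6.48 (SE 0.84, 0.0039) for stat1b, 6.33 (SE 0.59, 0.00098) for dhx58, 6.66 (SE 0.76, 0.0019) for rsad2 and 6.43 (SE 0.62, 0.001) for mxa. Several of these folds depend on single libraries: without A80 the log2 fold change was 8.37 for stat1b, 8.86 for rsad2, 7.48 for dhx58, 7.14 for mxa and 8.46 for mxe, and without A74 it was 5.75 for stat1b, 5.69 for mxa, 5.79 for mxb and 5.67 for mxe.

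Outside the fixed interferon list, aste1a rose 127-fold (69.8 ± 47.6 against 0.544 ± 0.678 CPM, n = 3) and HERC5, named for a ligase of the ISG15 system, 111-fold (log2 6.99 and 6.8, with 8.81 and 8.12 without A80, 6.27 and 5.94 without A74, and 6.21 for HERC5 without A79). The gene listed as SHISA4 (1 of many) held 142, 124 and 508 counts in the 3 stimulated ifih1mut libraries and 0, 1 and 3 in the stimulated control libraries, too few for a firm fold. The members ifit10 and ifit8 of the IFIT family were 121-fold and 76.1-fold higher, from levels of 0.0705 and 0.202 CPM that rest on few counts, and the log2 fold change of ifit10 went from 6.92 to 8.96 without A80 and 6.3 without A74, and that of ifit8 from 6.25 to 5.46 without A74. Of 3 genes that were lower, ern1 (chromosome 3, 55420176 to 55481157), the IRE1 sensor of the unfolded protein response, was lower by 0.88 on the log2 scale (SE 0.14, edgeR adjusted p = 0.015) and glod4 by 1.23 (SE 0.2, 0.016). The level of ern1 was 35.4 ± 6.52 CPM in control and 23.2 ± 1.94 CPM in ifih1mut pools, and 39 ± 2.3 and 21.2 ± 2.43 CPM with poly I:C (SD, n = 3), so it was also lower without poly I:C, where it was not called. With poly I:C the call of ern1 was lost without A72, A74, A79 or A80 and that of glod4 without A73, A74, A78 or A79 (edgeR adjusted p from 0.051 to 0.092). The third, an assembled gene without a name on an alternate contig, was lower by 1.48 and was chosen after its values were seen.

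By list, 30 of 49 interferon-stimulated genes passed over all genes and 41 adjusted over the list alone, 48 of 49 had a positive log2 fold change, and the median was 2.57 (camera adjusted p = 0.00107 with an estimated correlation). Of 21 genes of RNA sensing, 5 of which are also in the interferon-stimulated list, 5 rose (8 adjusted over the list alone, median 0.60, camera adjusted p = 0.00448 with an estimated correlation). They include irf7 (8.23-fold), irf3 (7.63-fold) and the Z-DNA-binding kinase pkz (22-fold), whose log2 fold change went from 4.46 to 3.51 without A74. Of 22 genes of MHC class I presentation, 3 rose (14 adjusted over the list alone, median 1.05, adjusted p = 0.00822 with an estimated correlation): the peptide-loading gene tapbp.1 (2.87-fold), the proteasome activator psme2 (3.78-fold) and the peptide-trimming enzyme erap1a (2.05-fold). Of the 22, 6 rose with the set block. Of 18 genes of interferons, receptors and JAK-STAT, 2 rose, stat1b and stat1a (2.13-fold), both also in the interferon-stimulated list (4 adjusted over the list alone, median 0.13, adjusted p = 0.0105 with an estimated correlation). The calls of tapbp.1, psme2, erap1a and stat1a were lost without A72, A74, A78, A79 or A80 and that of irf3 without A74, A78 or A79 (edgeR adjusted p from 0.053 to 0.22).

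Of 23 macrophage and microglia markers, 1 rose, lgals3bpb (5.51-fold), with 5 adjusted over the list alone and a median of 0.56, and with the set block 3 rose, 9 adjusted over the list alone. This list's camera adjusted p was 0.0372 with an estimated correlation and 0.252 when the set block was added. Inflammatory cytokines and NF-kB had 0 called members of 42 in edgeR (1 adjusted over the list alone, 4 with the set block) and a median of 0.22, called at the preset correlation (camera adjusted p = 0.000369) and not with an estimated one (adjusted p = 0.658). In that list il1b stood at 3.76 ± 4.03 CPM against 3.27 ± 3.04 CPM and cxcl8a at 3.65 ± 0.824 against 4.04 ± 0.748 CPM (SD, n = 3). The cytokine tnfa, with 52 counts in the 12 libraries together, was not tested. At the preset, camera also called liver genes (median -0.24, adjusted p = 3.64e-06), lens crystallins (0.16, 0.00364) and neuron and glia genes (-0.1, 0.0118). Exocrine pancreas (-0.17), photoreceptor (0.15) and inflammasome and pyroptosis genes (0.2) each had a preset adjusted p of 0.0374. With an estimated correlation none of these passed (camera adjusted p of 0.29 or above).

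In all, 156 genes were higher and 3 lower in edgeR (9 lower with the set block, 17 in DESeq2 and 51 in DESeq2 with the block), with 992 at an unadjusted p under 0.05, and 159 of 159 kept their direction in each of the 3 sets. These genes were called on the same libraries, so that agreement was largely fixed in advance and is no separate support. The medians of the interferon-stimulated list within the sets were 1.5, 1.77 and 2.45 on the log2(CPM + 0.5) scale. The count was 70 without A79, 78 without A78, 81 without A80 and 102 without A74, 0 without set 2, and 272 in DESeq2. The authors' deposited table gave 261 genes, of which 157 were among the 159.

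**Figure D2:**
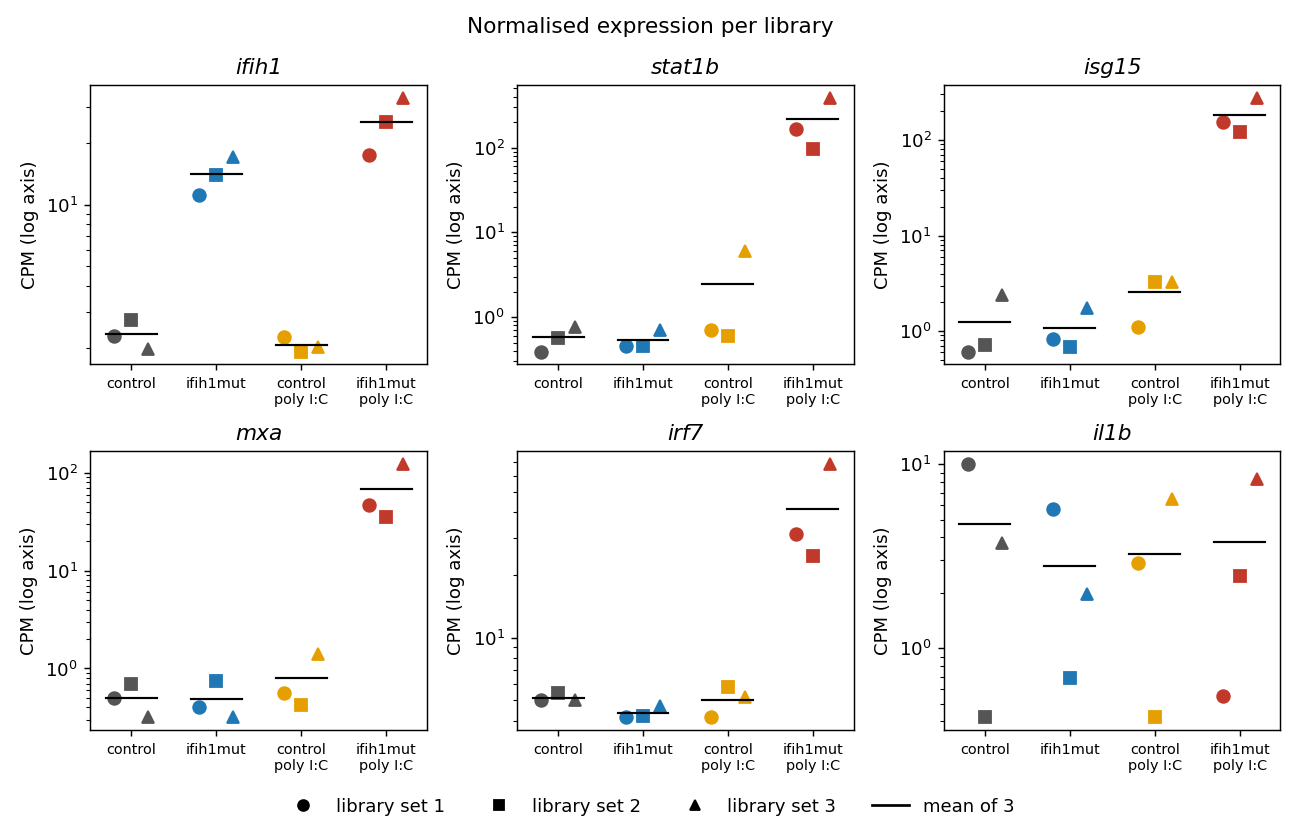
CPM of 6 genes in each of the 12 libraries (log axis) by group, with the marker for the library set and a line at the mean of 3 libraries. For stat1b the stimulated ifih1mut libraries lie between 96.2 and 389.5 CPM and the stimulated control library A80 at 5.994 CPM, while il1b overlaps in all groups.

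The fourth question was what poly I:C does in ifih1mut larvae. The same kinds of genes rose against unstimulated ifih1mut pools. The transcript of isg15 rose 168-fold (log2 7.39, SE 0.66, edgeR adjusted p = 0.00042), stat1b 396-fold (log2 8.63, SE 0.94, 0.001), dhx58 253-fold (log2 7.98, SE 0.64, 0.00028) and rsad2 240-fold (log2 7.90, SE 0.80, 0.00073). The kinase gene cmpk2, next to rsad2 on chromosome 17, rose 207-fold, aste1a 327-fold, the helicase gene helz2 86.1-fold and the apoptosis regulator xaf1 47-fold. The folds were 9.55 for irf7, 6.38 for lgals3bpb and 2.37 for stat1a. The ifih1 transcript itself was 1.8-fold higher (log2 0.85, SE 0.23), which did not pass (edgeR adjusted p = 0.27) and did in DESeq2 (adjusted p = 0.049). Without A74 the log2 fold change was 7.9 for stat1b, 6.9 for cmpk2 (from 7.69) and 7.64 for aste1a (from 8.36).

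Of the interferon-stimulated genes, 31 of 49 rose (43 adjusted over the list alone, median log2 fold change 3.24, camera adjusted p = 0.00061 with an estimated correlation). Of the RNA sensing genes 6 of 21 rose (7 adjusted over the list alone, median 0.45, adjusted p = 0.00291 with an estimated correlation), with pkz at 28.6-fold (log2 4.84, and 3.89 without A74) and irf3 at 7.32-fold. Of the MHC class I genes 4 of 22 rose (14 adjusted over the list alone, median 0.99, adjusted p = 0.00608 with an estimated correlation): psme2, erap1a, the peptide transporter tap2a (13.6-fold) and b2m, the light chain of MHC class I (6.45-fold). In the fit with the set block 8 rose. Without A74, A75 or A77, irf3, psme2, erap1a, tap2a and b2m lost their call, as did tap2a, b2m and stat1a without A76, erap1a and b2m without A72, and stat1a without A77 (edgeR adjusted p from 0.062 to 0.26), and the log2 fold change of tap2a went from 3.76 to 2.92 without A74. Of the interferon and JAK-STAT genes 2 of 18 rose, again stat1a and stat1b (6 adjusted over the list alone, median 0.19, adjusted p = 0.00389 with an estimated correlation), and 5 with the set block. The macrophage and microglia list had 1 member of 23 called (3 with the set block) and 5 adjusted over the list alone, with a median of 0.44 (adjusted p = 0.0234 with an estimated correlation, 0.17 with the set block added). Exocrine pancreas genes had a median of -0.65 with 0 members called in edgeR (camera adjusted p = 4.91e-09 at the preset, adjusted p = 0.151 with an estimated correlation). Of its 20 members, 3 were lower with the set block, 12 adjusted over the list alone, with a median of -0.58 and an adjusted p of 0.0617 in camera with an estimated correlation and 0.0184 in fry.

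In all, 181 genes were higher and 2 lower in edgeR (18 lower with the set block, 16 in DESeq2 and 88 in DESeq2 with the block), and 183 of 183 kept their direction in each of the 3 sets, which calling them on these same libraries made likely. The lower ones, si:dkey-4p15.5 at -0.48 on the log2 scale and an unnamed assembled gene at -0.58, were chosen after their values were seen. The count with the set block was 277, which included the 183. The medians of the interferon-stimulated list within the sets were 1.73, 1.75 and 2.9 on the log2(CPM + 0.5) scale. The count was 92 without A77, 105 without A75, 107 without A76 and 116 without A74, between 49 and 89 without 1 of the sets, and 307 in DESeq2.

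The last question was whether the response to poly I:C differs between the genotypes, tested as the difference of the poly I:C effects. Interferon-stimulated genes responded more in ifih1mut pools. On the log2 scale the poly I:C effect was larger by 6.18 for isg15 (SE 0.85, edgeR adjusted p = 0.025), by 6.51 for dhx58 (SE 0.85, 0.024), by 6.47 for mxa (SE 0.87, 0.025), by 7.11 for mxb (SE 1.03, 0.03), by 7.79 for ifit10 (SE 1.13, 0.03) and by 3.29 for irf7 (SE 0.44, 0.025). For stat1b the difference was 6.44 (SE 1.25, edgeR adjusted p = 0.12) and for rsad2 6.31 (SE 1.2, 0.1), and these passed with the set block (edgeR adjusted p = 0.0033 and 0.011). Without A80 they were 8.33 and 8.51 (edgeR adjusted p = 0.018 and 0.013), and without A74 they were 5.72 and 5.73. The calls of isg15, dhx58, mxa, mxb, ifit10 and irf7 were all lost without any 1 of A81, A82, A83, A75, A76, A77, A78 or A79 (edgeR adjusted p from 0.061 to 0.24), and those of isg15, mxb and irf7 also without A80 (from 0.053 to 0.06). Over the 12 fits with 1 library left out the log2 differences ran from 6.02 to 7.66 for dhx58, from 5.72 to 7.17 for mxa, from 6.11 to 7.52 for mxb, from 5.42 to 6.75 for isg15, from 7.13 to 9.83 for ifit10 and from 2.72 to 3.55 for irf7. The ends over 1.5 times away lay without A80 for dhx58, mxa and ifit10, without A74 for mxa, mxb and ifit10, and without A83 for isg15. For il1b the log2 difference was 1.01 (SE 1.7) and for cxcl8a 0.17 (SE 0.65), both at an adjusted p of 1 in edgeR. The value of il1b was -0.32 without A74 and 2.05 without A75, and that of cxcl8a was -0.49 without A81.

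The interferon-stimulated list had 13 of 49 members called (24 with the set block, 38 adjusted over the list alone) and a median difference of 3.1 (camera adjusted p = 0.000881 with an estimated correlation). Its set medians, on the log2(CPM + 0.5) scale, were 1.95, 1.72 and 2.4. The RNA sensing list had 2 of 21 (4 with the set block, 6 adjusted over the list alone, median 0.53, adjusted p = 0.00395 with an estimated correlation). The MHC class I list had 0 of 22 called in edgeR (5 adjusted over the list alone, 11 with the set block, median 0.99) and the interferon and JAK-STAT list 0 of 18 (3 with the set block; 3 adjusted over the list alone, 5 with the block; median 0.11), each with a camera adjusted p of 0.0129 with an estimated correlation. In fry their adjusted p was 0.0647 and 0.0758, and 0.045 and 0.0382 with the set block. The macrophage and microglia list had 1 of 23 over all genes and 1 adjusted over the list alone (3 with the set block), a median of 0.54 and an adjusted p of 0.0507 with an estimated correlation. Inflammatory cytokines and NF-kB had 0 of 42 called and a median of 0.37, positive in 33 members. The camera adjusted p of that list was 3.48e-05 at the preset and 0.467 with an estimated correlation. Altogether 41 genes were higher and 0 lower in edgeR, with 542 at an unadjusted p under 0.05, while DESeq2 gave 133 higher and 3 lower. The set block gave 79 called genes, which included the 41, and 41 of 41 had the same direction in each set, which calling them on these same libraries made likely. The count was 0 without any of A81, A82, A75, A76, A77, A78 or A79, 6 without A83 and 22 without A80, and it was 0 without set 1 or set 2 and 15 without set 3.

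**Figure D3:**
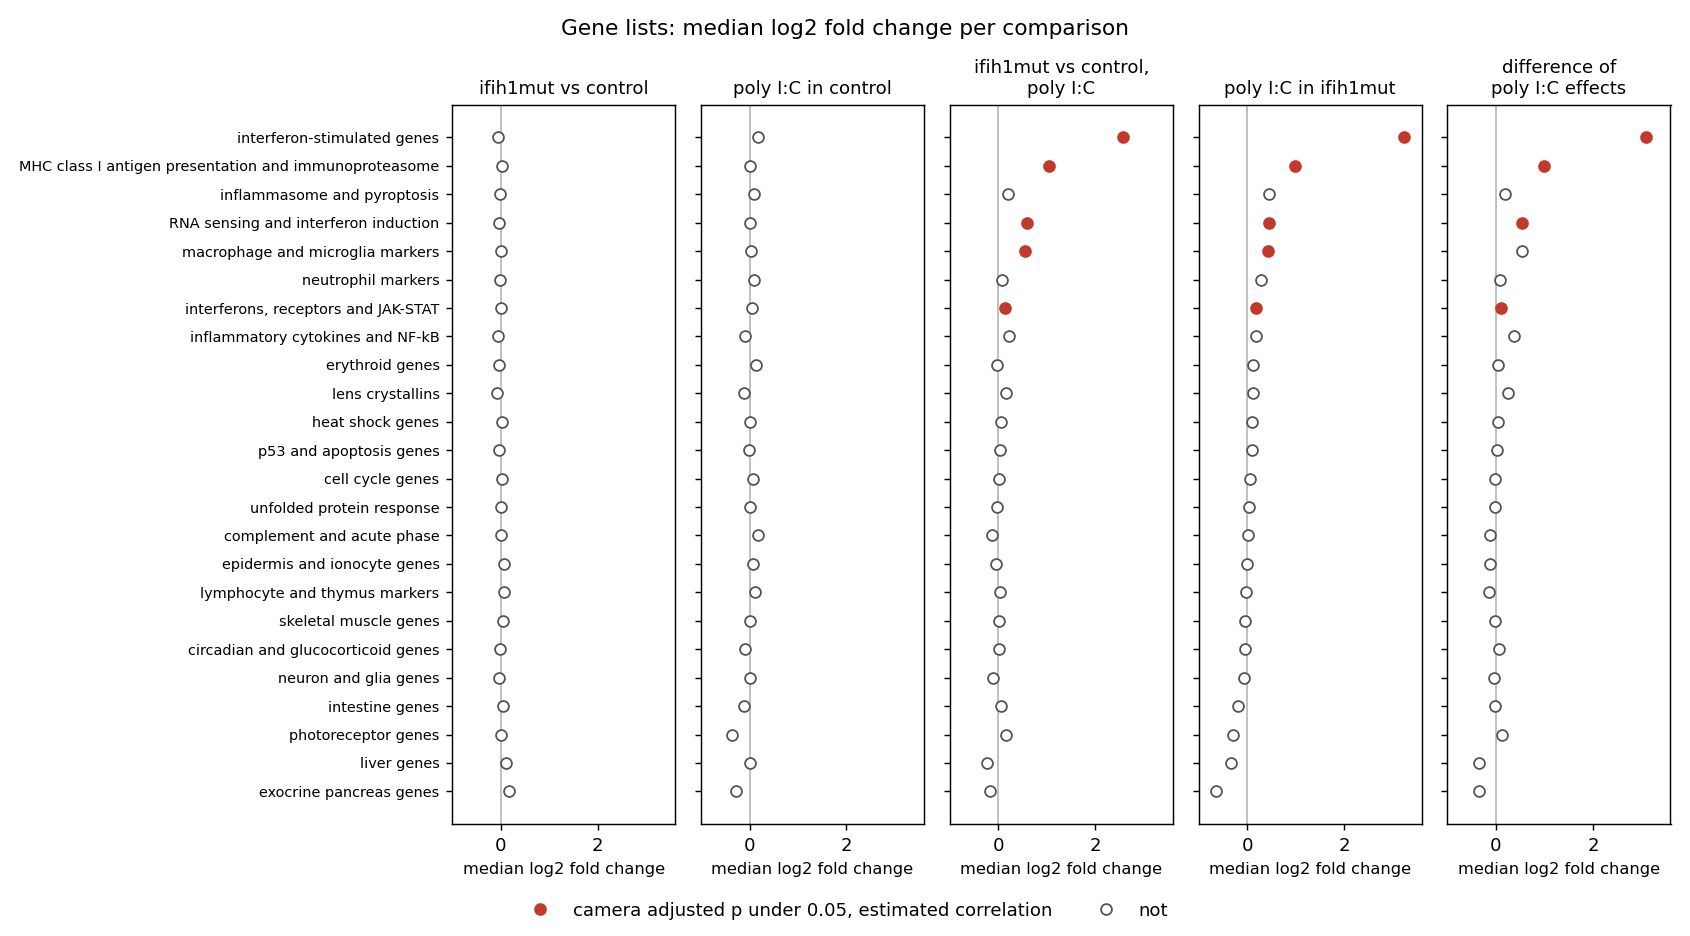
Median log2 fold change of the members of each of 24 gene lists in the 5 comparisons, with filled points for lists past a camera adjusted p of 0.05 with an estimated correlation. The interferon-stimulated list stands at -0.06 and 0.17 in the first 2 comparisons and at 2.57, 3.24 and 3.1 in the others.

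The comparisons were also set against each other. Of the genes higher in ifih1mut than control with poly I:C and those higher with poly I:C in ifih1mut, 143 were shared, where independent lists of 156 and 181 genes give 1.07. Both comparisons use the 3 stimulated ifih1mut libraries, and part of the excess may come from them. Across 26508 genes, which are not independent replicates, the log2 fold changes of ifih1mut against control without and with poly I:C had r = -0.001 and rho = 0.09, in comparisons with no shared library (simulated unchanged groups gave r = -0.007 and rho = -0.004). Those of ifih1mut and of poly I:C in control larvae, which share the 3 control libraries, had r = 0.34 and rho = 0.259, below the simulated 0.481 and 0.451, and the covariance was 0.023 against a simulated 0.0384.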

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

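Of the tests in this part, those of a single library, of depth, of whether poly I:C reached the control pools and of other splits of the libraries were chosen after the results were seen. The results below stood out because the effect of poly I:C differed between the genotypes in a test of the difference itself. It differed for 41 genes in edgeR, with log2 differences of 7.79 for ifit10, 7.11 for mxb, 6.51 for dhx58, 6.47 for mxa, 6.18 for isg15 and 3.29 for irf7. By list, the median differences were 3.1 for interferon-stimulated genes, 0.99 for MHC class I antigen presentation, 0.53 for RNA sensing and 0.11 for interferons, receptors and JAK-STAT. Of the 18 tested members of the last list, 5 are also in the interferon-stimulated list, as are 5 of 21 of RNA sensing. These 2 lists are therefore not separate from it. The mean difference of the interferon and JAK-STAT list was 0.83. No group had the 4 libraries that a test for single outlying samples needs.

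The larger response of interferon-stimulated genes in ifih1mut pools was weighed against 3 technical explanations. The tables argue against a single library, since the median difference of the list stayed at or above 2.6 on the log2 scale without each of the 12 libraries. They also argue against unequal depth, since the median was 3.07 after thinning to the shallowest library and 3.1 before. It stays open whether poly I:C acted in the control pools. The list's camera adjusted p there was 0.75 with an estimated correlation. In A80, stat1b, rsad2, dhx58 and mxe stood at 5.994, 1.807, 3.494 and 2.048 CPM, above the highest unstimulated control pool (0.7561, 0.2674, 0.7163 and 0.441 CPM). The level of isg15 was 3.3 CPM in A79 and 3.283 in A80, against at most 2.394 in unstimulated control pools, but 1.113 in A78. Of 49 list members, 12 were higher in all 3 sets and 4 were lower in all 3. These are a few genes, mostly in 1 pool. For the group a lower response and a missed stimulation cannot be told apart without a gene known to respond in control larvae. A biological reading, that ifih1mut larvae may respond more to the same stimulus, remains a hypothesis beside it.

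Other splits of the same libraries were counted for each comparison. With 3 against 3 libraries there are 10 splits, too few for a share under 0.05. For ifih1mut against control the real split gave 1 gene and the highest other 1 (2 of 10 as large), for poly I:C in control larvae 0 and 0 (10 of 10), for ifih1mut against control with poly I:C 159 and 52 (1 of 10), and for poly I:C in ifih1mut larvae 183 and 1 (1 of 10). For the difference of effects, 100 of 200 splits that reassign poly I:C within each genotype were drawn, and 8 gave at least 41 genes, the highest other giving 76, so chance is not excluded by this count. The other 7 all kept the stimulated and unstimulated ifih1mut pools apart, as labelled or with the labels swapped, and so carry the effect in those pools; the one with 76 swapped these labels and left the control pools as labelled. The highest count without that division was 0. These splits mix the library sets; of the 32 splits that exchange poly I:C labels only within a genotype and set, fitted with the set block, 6 gave at least the real 79 genes, the highest other giving 141 with the ifih1mut labels swapped in every set, so chance is not excluded there either. Those 6 also kept the ifih1mut pools apart, and without that division the highest count was 0.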

How the results depend on the processing

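The library-set block, DESeq2 with that block, leaving out each set and thinning were chosen after the data were seen; the other alternatives were fixed before. No paired analysis was possible because the table columns do not carry the replicate numbers of the titles, and the library-set block, which was found in the data, stands in for one. Of 2952 values under an alternative, 16 reversed, and those were gene lists with 1 library left out. A value counted as reversed only if its direction turned and the main fit or the alternative called it. Genes called in neither could turn without being counted, as il1b and cxcl8a did without A81 in ifih1mut against control. RLE size factors, an unfiltered fit, the minimum CPM, the added fold change and thinning moved no total of called genes by over 1.5 times, and the minimum CPM moved the correlations of fold changes from -0.001 to 0.012 and from 0.34 to 0.307. Lists were retested at the preset correlation with RLE size factors, the set block, thinning and 1 library left out. The main and set-block fits were also tested with an estimated correlation and with fry. In each of these the interferon-stimulated list kept its call in the 3 comparisons with stimulated ifih1mut pools. At the preset its camera adjusted p there was 6.15e-218 or lower in the main fit, so a lost call was unlikely. The other alternatives, leaving out each set among them, gave no list test.

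Counts of genes moved as follows, in the order ifih1mut against control, poly I:C in control, ifih1mut against control with poly I:C, poly I:C in ifih1mut and the difference of effects. DESeq2 gave 2, 0, 272, 307 and 136, of which 158, 182 and 41 in the last 3 were also called by edgeR, and with the set block it gave 7, 24, 378, 450 and 183. The block in edgeR gave 277 and 79 in the last 2 and changed no other total by over 1.5 times. Genes called lower moved more than the totals: for ifih1mut against control with poly I:C they were 3 in edgeR, 9 with the block, 17 in DESeq2 and 51 in DESeq2 with the block, and for poly I:C in ifih1mut 2, 18, 16 and 88. Only the groups compared gave 0, 0, 69 and 99 in the first 4, with fewer residual degrees of freedom. Without set 1 the counts were 0, 0, 36, 89 and 0, without set 2 they were 0, 0, 0, 49 and 0, and without set 3 they were 0, 0, 52, 54 and 15, with fewer libraries. With 1 library left out they ranged from 0 to 1, from 0 to 0, from 70 to 177, from 92 to 201 and from 0 to 60. Those fits had no set block and left the library sets unbalanced over the groups. The cause was not tested where no cause is named.

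The log2 fold change of ifih1 lost its call against control at 2.58 with only the groups compared and at 2.7, 2.71 and 2.32 without sets 1, 2 and 3, with a range of 2.41 to 2.72 when 1 library was left out. With poly I:C it lost it at 3.57 without set 2 (range 3.37 to 3.83). For poly I:C in ifih1mut it gained a call at 0.85 in DESeq2 and 0.84 in DESeq2 with the block (range 0.61 to 1.07). In control larvae given poly I:C, the adjusted p of the interferon-stimulated list was 0.75 in camera with an estimated correlation and 0.94 in fry. At the preset correlation the camera adjusted p was 0.000684 with all libraries. With 1 library left out it ran from 2.2e-06 to 0.6 at the preset, the highest without A80.

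Preset camera adjusted p-values of lists whose direction reversed, with 1 library left out, ran as follows. For ifih1mut against control they ran from 2.3e-05 to 0.9 for cell cycle, from 3.4e-05 to 0.74 for circadian and glucocorticoid, from 1.9e-11 to 0.68 for liver, from 6.1e-05 to 0.97 for intestine and from 0.00081 to 0.99 for epidermis genes. For poly I:C in control they ran from 1.3e-08 to 0.89 for intestine and from 5.5e-06 to 0.73 for cell cycle genes, and for ifih1mut against control with poly I:C from 5.8e-07 to 0.65 for photoreceptor genes. For poly I:C in ifih1mut they ran from 0.0043 to 0.8 for circadian, from 1.4e-06 to 0.97 for skeletal muscle and from 0.00084 to 0.84 for lens genes, and for the difference of effects from 0.0024 to 0.91 for circadian genes. These lists had no call with an estimated correlation. Leaving out 1 library without a set block unbalances the library sets, and whether that caused the reversals was not tested. Between set 3 and set 2 the median log2 difference was 0.78 for circadian, -0.59 for intestine, -0.33 for cell cycle and -0.28 for liver genes. It was 0.27 for skeletal muscle, -0.24 for photoreceptor, -0.13 for epidermis and 0.02 for lens genes. Depth leaves low genes untested, such as ifnphi2, ifnphi3, ifnphi4 and tnfa with 14, 88, 8 and 52 counts in the 12 libraries together.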

Other observations

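Of the tests in this part, those of library depth, of shared parents, of the time of day and of a haplotype were fixed before their values were seen, while the test of chromosome 3 was chosen after. Each pattern was noticed in the data first, and the higher repressor genes of the clock in set 3, the share of alternate contigs among genes of set 1 and some clusters of neighbouring genes had been seen before these tests were fixed.

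Transcripts of the type I interferons themselves stayed near the limit of detection in whole larvae. These genes, and adar, were chosen after their values were seen. Over the 12 libraries together, ifnphi2 had 14 counts, ifnphi3 88 and ifnphi4 8, too few to be tested. The one tested, ifnphi1, was at 0.17 ± 0.075 CPM in control, 0.183 ± 0.11 in ifih1mut, 0.322 ± 0.259 in control with poly I:C and 0.635 ± 0.435 CPM in ifih1mut with poly I:C (SD, n = 3), and no comparison called it in edgeR. The editing enzyme adar, which acts on double-stranded RNA, was higher in stimulated ifih1mut pools than in stimulated control pools (log2 0.77, SE 0.14, edgeR adjusted p = 0.035) and than in unstimulated ifih1mut pools (log2 0.79, SE 0.14, 0.027).

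Macrophage and microglia markers apart (1 member called, adjusted p = 0.0234 with an estimated correlation), the lists of larval tissues and stress programmes had 0 members called by edgeR in ifih1mut pools given poly I:C, and none passed with an estimated correlation. Under the set block, edgeR called 3 lower exocrine pancreas genes, 1 lower epidermis and ionocyte gene, 1 lower neuron and glia gene, 2 higher complement and acute phase genes, 1 higher inflammasome gene and 1 higher inflammatory cytokine or NF-kB gene, and none of these tissue and stress lists passed with an estimated correlation (exocrine pancreas adjusted p = 0.0617, macrophage and microglia 0.17). Adjusted over the list alone, the block gave 11 lower liver genes and 5 lower photoreceptor genes, and 0 of each were lower without it. It also gave 4 higher and 5 lower complement and acute phase genes, against 1 higher and 0 lower without it. At the preset correlation, camera called liver genes (median log2 fold change -0.33, positive in 3 of 30 members, adjusted p = 2.74e-08, 0.273 with an estimated correlation), photoreceptor genes (-0.29, 3.65e-06, 0.526 estimated), skeletal muscle genes (-0.05, 0.0496, 0.651 estimated), lens crystallins (0.12, 0.0083, 0.552 estimated) and neutrophil markers (0.28, 0.0078, 0.273 estimated). Inflammasome and pyroptosis genes had a median of 0.46 (2 of 11 adjusted over the list alone, 0.00121, 0.0707 estimated). Inflammatory cytokines and NF-kB had a median of 0.18, positive in 35 of 42 members (camera adjusted p = 8.57e-05 at the preset, 0.505 estimated). Neither setting called intestine genes (median -0.19), neuron and glia genes (-0.06), circadian and glucocorticoid genes (-0.05), lymphocyte and thymus markers (-0.02), epidermis and ionocyte genes (0), complement and acute phase (0.01), unfolded protein response (0.03), cell cycle genes (0.05), p53 and apoptosis genes (0.09), heat shock genes (0.1) or erythroid genes (0.13).

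The resemblance of libraries across groups by their position in the numbering was the strongest structure in the data. Unequal depth does not account for it, since after thinning to 31876869 counts the lowest correlation at the same position was 0.274 and the highest at different positions 0.134. Different parents of set 1 are a candidate explanation: 4403 genes differed between set 1 and the others in edgeR, and of the 552 leading ones on chromosomes 35.5% had a neighbour within 100 kb that also differed, 3.19 times the share of random genes, against 1.34 times for set 3 and set 2. Another time of day for set 3 stays open only by a condition added later. In the clock's repressor arm 8 genes had a median log2 difference of 1.06, all 8 above 0. In the activator arm 4 genes had one of 0.0031 with an SE of 0.08. The rule fixed before counted medians of the same sign, as here, against this explanation. Weighing the activator median against its spread was decided after it was seen, and leaves the test undecided. The labels give neither clutch nor hour, and no biological explanation by group was tested.

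Genes at an unadjusted p under 0.05 between ifih1mut and control pools with the set block, ifih1 left out, numbered 349, of which 208 were lower. Chance alone gives 1325 of 26508 genes at this threshold, and only ifih1 was called. The 349 are therefore not shown to differ one by one. A haplotype carried with the transgene may contribute: 61.9% of the 349 kept their sign between the genotypes with poly I:C, in other libraries, against 54.9% of all tested genes. Of the 226 outside alternate contigs and unnamed assembled genes, ifih1 included, 14.6% had a neighbour within 100 kb among them, 3.07 times the random share of 4.75%. For poly I:C in control larvae the share was 22.5% of 755 genes, 1.5 times a random 15%. The random share grows with the number of genes, so these ratios are not on equal terms. Of the 349, 49 had the same sign and an unadjusted p under 0.05 in both conditions. On chromosome 3 lay 16 of these 49, where 2.1 were expected (Fisher's exact test, adjusted p = 3.5e-09 over 25 chromosomes). From 44 to 60.3 Mb lay 14 of the 16. Among those 14 were ern1 and, chosen after their values were seen, nprl3 and the embryonic globins hbbe1.1 (log2 1.47 and 1.69) and hbbe1.2 (-0.76 and -1.41). Fisher's exact test treats genes as independent, which neighbouring genes are not, so its p-values in this paragraph overstate the evidence. A line difference in a region of chromosome 3 is a candidate explanation for part of the 349: chosen from the libraries without poly I:C alone, the chromosome held 33 of them where 15.3 were expected (Fisher's exact test, adjusted p = 0.00084), and 26 of the 33 kept their sign in the other libraries against 190 of 316 elsewhere (permutation p = 0.032 by rotating the signs along the genome). The rotation replaced earlier forms of the test after their values were seen. Fisher's exact test on the same counts had given p = 0.039, and another form, which conditioned on the outcome, had found no difference. The other libraries belong to the same library sets, and no genotype data were used.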
